A study of Mus musculus with 6 samples.

How the data were processed

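Transcript levels were measured in 6 RNA samples of the mouse B lymphoma line CH12F3-2A, each on its own single-channel oligonucleotide array read at 635 nm. The samples form 3 groups of 2 by their titles: Control, siBrd4 and JQ1. Per the labels' protocols, siRNA was electroporated 24 h before stimulation, and JQ1 or its solvent DMSO was present during the 24 h of stimulation. Total RNA was amplified to amino allyl aRNA and coupled to a Cy5 dye, and the coupling and fragmentation followed a protocol of the array maker Toray, per the labels' protocols. The labels do not say whether the siBrd4 samples also had DMSO, or whether the JQ1 samples also had a control siRNA. A single group, named only Control in the titles, served both comparisons, so its match to each treatment could not be checked. The labels also do not say whether replicates came from separate cultures. The p-values therefore measure the spread between these samples, which may be technical.

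Per the file headers, each deposited scanner file holds the intensity of every spot as the median pixel brightness, with no background taken off, and a second intensity for the area around the spot. The authors also deposited a table of processed intensity values on a linear scale. The steps behind that table are not given in the sources used here. Set against the scanner values, each of its columns was a straight line of that array's spot medians, with slopes from 0.657 to 0.762, a correlation of at least 0.999991 across probes and a zero between 10.6 and 11.5, near the mean of the blank spots. Its column medians lay between 24.9944 and 25, and 1705 to 2538 probes per column had no value.

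Each array held 27456 spots, of which 23474 carried 23473 probes and 2736 were blank. A single spot was marked as bad on each of 3 arrays, and these spots were left out. Blank spots averaged 11.0 to 11.9 intensity units, and the median probe signal was 35 to 41. A probe counted as above background on an array when its spot median exceeded the mean of that array's blank spots by 2 SD. By that limit, 82.5% to 85.0% of probes were above background on an array. The number of arrays limits the precision: with 2 per group the fit had 3 residual degrees of freedom. Both siBrd4 arrays were scanned at a detector gain of 37 and the other 4 arrays at 36, so the gain differed with the group.

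Intensities were corrected with limma's normexp method and an added offset of 50. They were then averaged over spots of the same probe, put on the log2 scale and quantile normalized between arrays. The plan did not say which background normexp should use. The mean of each array's blank spots was chosen after the files were inspected and before any test, because the brightness around a spot followed the spot's own signal, with Spearman correlations of 0.850 to 0.955 across probe spots. The surrounding brightness was run as an alternative added after seeing the data, and it removed nearly all calls. Of the 23473 probes, 19882 were above background on both arrays of at least 1 group and were tested, and 3591 were left out. The offset shrinks fold changes of dim probes, so folds in the deposited values are given beside the fitted ones.

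All 6 arrays entered limma's linear model (lmFit and eBayes, limma 3.58.1 in R 4.3.3), with the group as the only term. Probes with a Benjamini-Hochberg adjusted p under 0.05 over all tested probes were called, for siBrd4 against Control, JQ1 against Control and siBrd4 against JQ1. The test and the alternatives were chosen before the data were examined, except those named as added. The fit was tested on simulated data with 19882 probes and 200 changed probes in each of 5 runs per comparison. For siBrd4 against Control it recovered 49.3% of probes changed by 0.3 on the log2 scale, 97.3% of those changed by 0.6 and 100% of those changed by 1.2, and 6.28% of its calls were false. For JQ1 against Control the shares were 53.1%, 97.3% and 99.7%, with 5.23% false calls, and for siBrd4 against JQ1 52.5%, 97.6% and 100%, with 5.98% false calls. The simulated changes were added on the log2 scale after the offset and normalization, with independent normal noise of each probe's fitted spread. These shares therefore do not hold for changes in the intensity of dim probes, which the offset shrinks. Because both treatments share the Control arrays, 50 sets of unchanged groups were simulated with each probe's own fitted spread.

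The files do not pair probe identifiers with genes, and 0 of the 23473 identifiers matched the mouse gene table used here, which is of assembly GRCm38.p6. Results are therefore given by probe identifier. The level of Brd4, the planned single genes and the 32 gene lists fixed beforehand were not analysed here, nor were the planned list tests. The rule for named genes asked for the largest rises and falls among called genes whose treated arrays both lay beyond both arrays of the other group, with a gene symbol. Without symbols, the rule was applied to probes, with the 2 largest rises and the 2 largest falls of each comparison, a number set after the files were inspected.

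Alternatives covered the background correction, the offset, the normalization between arrays, the deposited values, the filter on dim probes, the replicate number as a block, the groups in the fit, the eBayes settings, the threshold and each array left out. Those added after seeing the data were the surrounding brightness as background, scaling before an added constant, normexp without an offset, block medians subtracted and separate Control arrays. A block for the scan was not run, because each scan time held 1 array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.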

Results

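The study asked how transcript levels change when Brd4, a bromodomain protein that binds acetylated histones, is removed from chromatin in stimulated B cells. CH12F3-2A is a mouse B lymphoma line that switches its antibody class to IgA when given CD40 ligand, IL-4 and TGF-beta together. Brd4 was targeted either by siRNA or with 40 nM JQ1, a small molecule that occupies the acetyl-lysine pocket of BET bromodomains. RNA from 2 Control, 2 siBrd4 and 2 JQ1 samples, all stimulated, was hybridised to arrays of 23473 probes. The median probe signal was 35 to 41 intensity units over blank spots at 10.97 to 11.87, and 82.5% to 85.0% of probes were above background. Probes are given by their identifiers, since the files do not pair them with genes, and the knockdown of Brd4 itself was therefore not checked here.

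The 3 groups separated in the expression data. The first principal component held 52.5% of the variance over the 19882 tested probes and placed the Control arrays at 15.51 and 15.04, the JQ1 arrays at -14.3 and -14.3, and the siBrd4 arrays between them at -3.75 and 1.85. The second component held 26.5% and set the siBrd4 arrays, at -11.2 and -13.3, apart from the other 4 arrays, which lay between 5.11 and 6.86. The siBrd4 arrays were also those scanned at the higher detector gain, so the siRNA and the gain cannot be told apart on this component. After each probe's mean was removed, the correlation across probes between replicates was 0.62 for Control, 0.34 for siBrd4 and 0.66 for JQ1. All pairs of arrays from different groups were below 0, but removing the mean itself pushes correlations between arrays below 0. Their sign is therefore no evidence that the groups differ. Replicate 1 of siBrd4 lay closer to the JQ1 arrays, at -0.08 and -0.15, than replicate 2 did, at -0.44 and -0.36. Probes are not independent replicates.

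**Figure D1:**
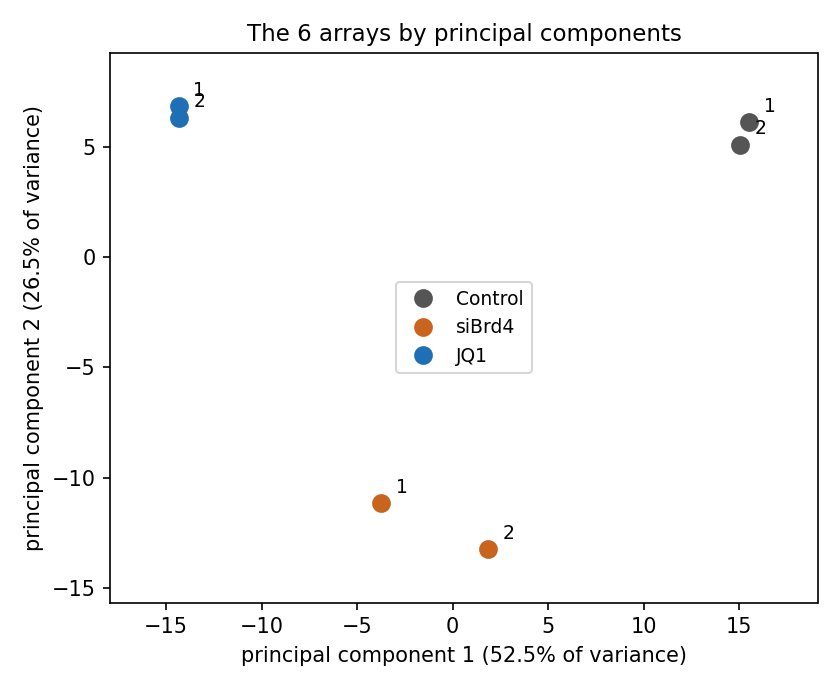
Position of each of the 6 arrays on the first principal component (horizontal axis, 52.5% of the variance) and the second (vertical axis, 26.5%) of log2 signal over the tested probes, with the replicate number beside each point. The siBrd4 arrays lie between Control and JQ1 on the first component, at -3.75 and 1.85, and apart from both on the second.

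The siBrd4 arrays were compared with the Control arrays to find the transcripts that change with the siRNA against Brd4. The largest fitted rise was that of probe M300010273, from a deposited intensity of 98.5 ± 9.36 (SD, n = 2) in Control to 554 ± 4.36 (SD, n = 2) in siBrd4. Its fitted log2 fold change was 2.21 with a standard error of 0.059 (limma adjusted p = 0.000561). Probe M300001635 rose from 343 ± 39.3 to 1209 ± 194 (SD, n = 2 each), a log2 fold change of 1.83 with a standard error of 0.12 (limma adjusted p = 0.00471). The largest fitted falls were those of M200000223, from 281 ± 40.2 to 62.3 ± 7.49, and of M400000336, from 153 ± 14.2 to 38.9 ± 2.39 (SD, n = 2 each). Their fitted log2 fold changes were -1.63 (limma adjusted p = 0.000986) and -1.25 (limma adjusted p = 0.00106). In the deposited values M200000223 stood at 0.222 of its Control mean and M400000336 at 0.254. Without Control replicate 2, M300010273 at 2.21 and M400000336 at -1.30 missed the threshold, and M300001635 missed it without Control replicate 1, at 1.86, and without Control replicate 2, at 1.80. With the brightness around each spot as background, M300001635 alone of these 4 passed, at 2.23, and M300010273 was at 1.41, M200000223 at -0.87 and M400000336 at -0.90.

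In all, 1627 of the 19882 tested probes (8.18%) passed limma's test for siBrd4 against Control, of which 816 rose and 811 fell. With the offset of 50, the median size among called probes was 0.36 on the log2 scale, a 1.28-fold difference, and 21 called probes changed at least 2-fold, with 18 rises and 3 falls. The number at least 2-fold depended on the offset: it was 51 of 1882 called probes with an offset of 10, 109 of 540 without an offset and 175 of 868 in the deposited values. At an unadjusted p under 0.05 there were 4733 probes, where chance alone gives 994. All 1627 called probes kept their direction with any single array left out. Such a fit also has fewer residual degrees of freedom, and the part of that and the part of particular arrays were not separated. The count was lower in each such fit, also without a JQ1 array, which is not among the groups compared here. It was also 1032 with median scaling (423 rises, 609 falls), 868 in the deposited values (235 rises, 633 falls), 592 with only the compared groups in the fit, 540 without the offset, 79 with plain subtraction and 1 when the brightness around each spot served as background, where 1353 of the 1627 probes kept their direction.

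The JQ1 arrays were compared with the same Control arrays to find the transcripts that change with the bromodomain inhibitor. The probes with the largest fitted rises were those of the siRNA comparison. M300001635 rose from 343 ± 39.3 to 1667 ± 132 (SD, n = 2 each), a log2 fold change of 2.25 with a standard error of 0.12 (limma adjusted p = 0.0009), and M300010273 rose to 527 ± 41.2 (SD, n = 2), a log2 fold change of 2.15 (limma adjusted p = 0.000143). The largest falls in the fit with the offset of 50 were those of M300005095, from 1658 ± 206 to 248 ± 56.7, and of M200000387, from 832 ± 33.0 to 119 ± 13.004 (SD, n = 2 each). Their log2 fold changes were -2.49 with a standard error of 0.15 (limma adjusted p = 0.00127) and -2.38 with a standard error of 0.11 (limma adjusted p = 0.000629). The probes with the largest fitted falls with the siRNA were also lower with JQ1, M200000223 at 23.3 ± 2.07 and M400000336 at 7.18 ± 0.235 (SD, n = 2 each). Their fitted log2 fold changes were -2.30 and -2.09 (limma adjusted p = 0.000143 for both), but in the deposited values their falls were the deeper: M400000336 stood at 0.0469 and M200000223 at 0.0831 of the Control mean, against 0.149 for M300005095 and 0.143 for M200000387. With the brightness around each spot as background, M300001635 passed, and M300010273 at 1.23, M300005095 at -2.01 and M200000387 at -1.90 did not.

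**Figure D2:**
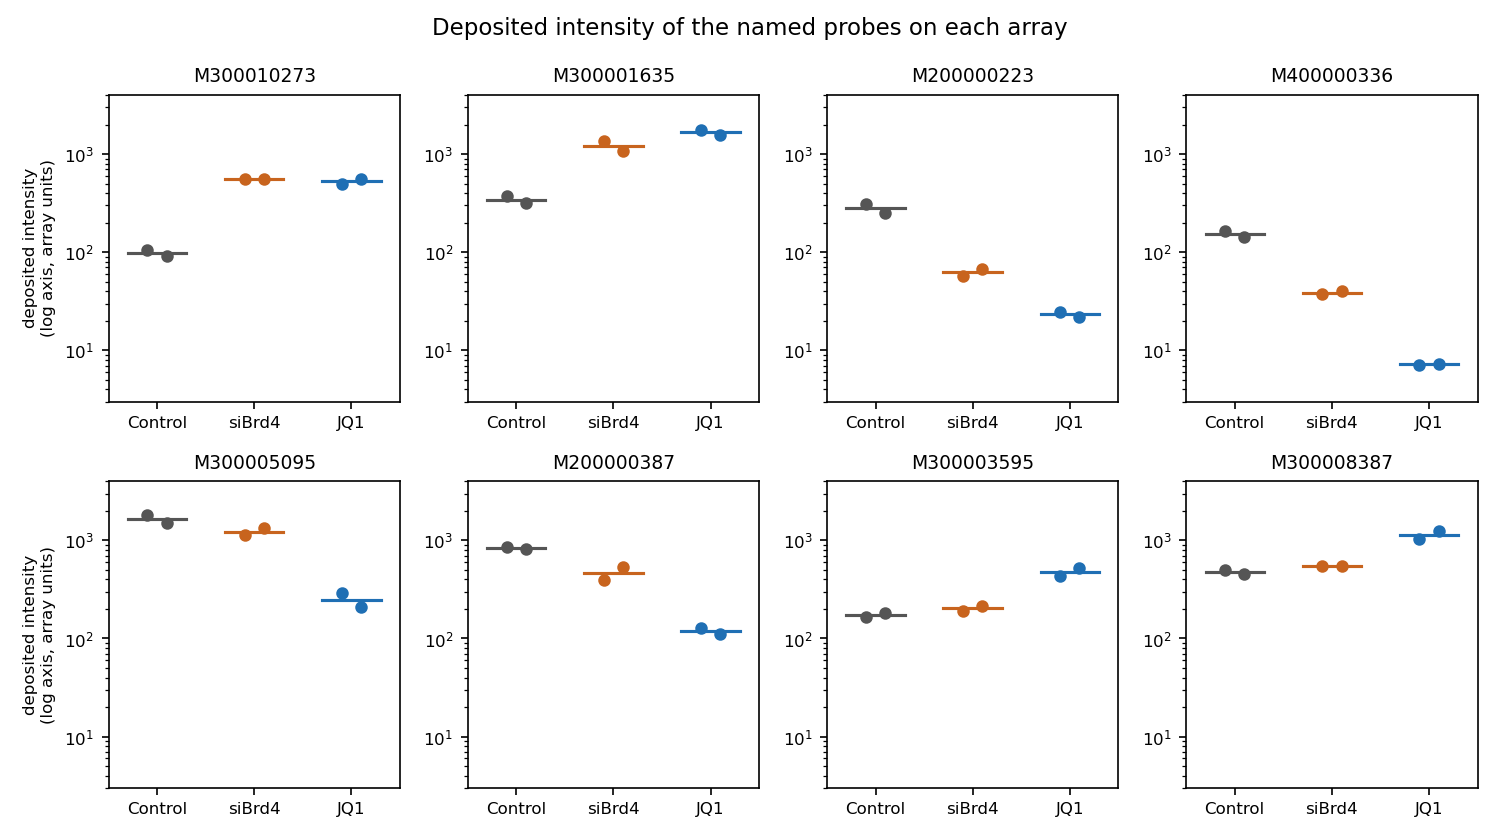
Deposited intensity of the 8 named probes (vertical log axis, array units) on each array of Control, siBrd4 and JQ1; points are single arrays and lines are group means of 2 arrays. M300010273 stands at 554 in siBrd4 and 527 in JQ1 against 98.5 in Control, whereas M300005095 stands at 1230 in siBrd4 and 248 in JQ1 against 1658 in Control.

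JQ1 against Control gave 2654 called probes (13.3%), of which 1175 rose and 1479 fell by limma's test. With the offset of 50, the median size among them was 0.37 on the log2 scale, and 68 changed at least 2-fold, with 37 rises and 31 falls. At least 2-fold changes were found for 186 of 2987 called probes with an offset of 10, 294 of 1496 without an offset, 390 of 820 with plain subtraction and 426 of 1645 in the deposited values. At an unadjusted p under 0.05 there were 5417 probes, where chance alone gives 994. In the brightest of 3 equal bins of mean signal 26.8% of probes were called with JQ1 and 17.1% with siBrd4, against 0.830% and 0.347% in the dimmest, where the median signal over the blanks was 7.19 units and the offset compresses changes. Without an offset the shares were 10.3% and 3.50% in the brightest bin and 4.42% and 1.75% in the dimmest, and with plain subtraction 4.72% and 0.332% against 3.15% and 0.513%. The count was 717 without Control replicate 1, 703 without Control replicate 2, 543 without JQ1 replicate 1 and 456 without JQ1 replicate 2. It was also 1645 in the deposited values, 1496 without the offset, 820 with plain subtraction and 1 with the brightness around each spot as background, and falls took a larger share under median scaling (476 rises, 2131 falls) and in the deposited values (382 rises, 1263 falls).

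**Figure D3:**
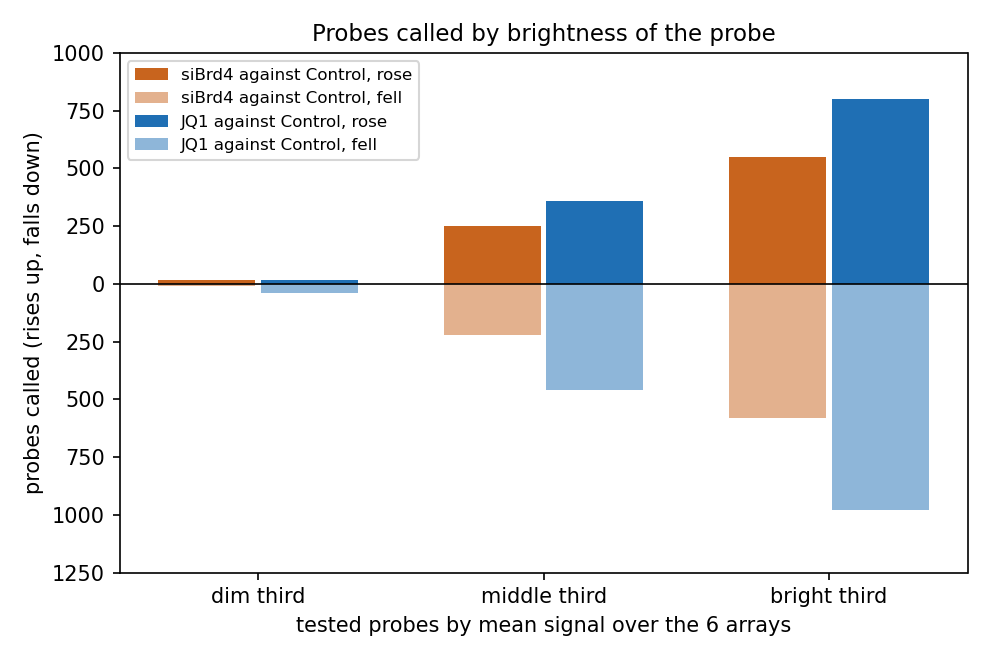
Number of called probes that rose (bars upward from 0) and fell (bars downward from 0) for siBrd4 and JQ1 against Control, in 3 equal bins of tested probes by mean log2 signal (horizontal axis). The brightest bin holds 1131 of the siBrd4 calls and 1778 of the JQ1 calls, and the dimmest 23 and 55.

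Since both treatments were used to deplete Brd4 from chromatin, their changes were set against each other. Among the called probes, 937 passed in both comparisons in the same direction, 405 as rises and 532 as falls, and 28 passed in opposite directions. Independent lists of these sizes would share 48.2 rises and 60.3 falls and have 108.6 probes in opposite directions. Simulated unchanged groups that share the Control arrays shared 0, but they had only 0.06 and 0.02 calls on average, so this value is no reference for the shared count. Part of the excess may come from the shared controls, since a split of the Control group leaves single arrays. The shared count was 21 without Control replicate 1, 1 without Control replicate 2, 275 without siBrd4 replicate 1, 181 without JQ1 replicate 1 and 157 without JQ1 replicate 2. It was also 386 with only the compared groups in the fit, 357 in the deposited values, 287 without the offset, 55 with plain subtraction and 1 with the brightness around each spot as background.

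Across the 19882 tested probes, the siBrd4 and JQ1 log2 fold changes had a Pearson correlation of 0.65 and a Spearman correlation of 0.54, and 68.1% of probes had the same sign. Unchanged groups that share the Control arrays gave 0.50, 0.47 and 66.6% in simulation. The covariance was 0.0233, against 0.00223 for unchanged groups, a difference of 0.0211. With each treatment set against a different Control array, the Pearson correlation was 0.51 and 0.53 for the pair of possible assignments. The covariance was 0.0200 and 0.0204. The simulated values are those of shared Control arrays and are no reference for this setting. The JQ1 changes were the wider, with an SD over probes of 0.210 against 0.171 for siBrd4. Among the 937 shared probes the median size was 0.44 with JQ1 and 0.39 with siBrd4 on the log2 scale.

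**Figure D4:**
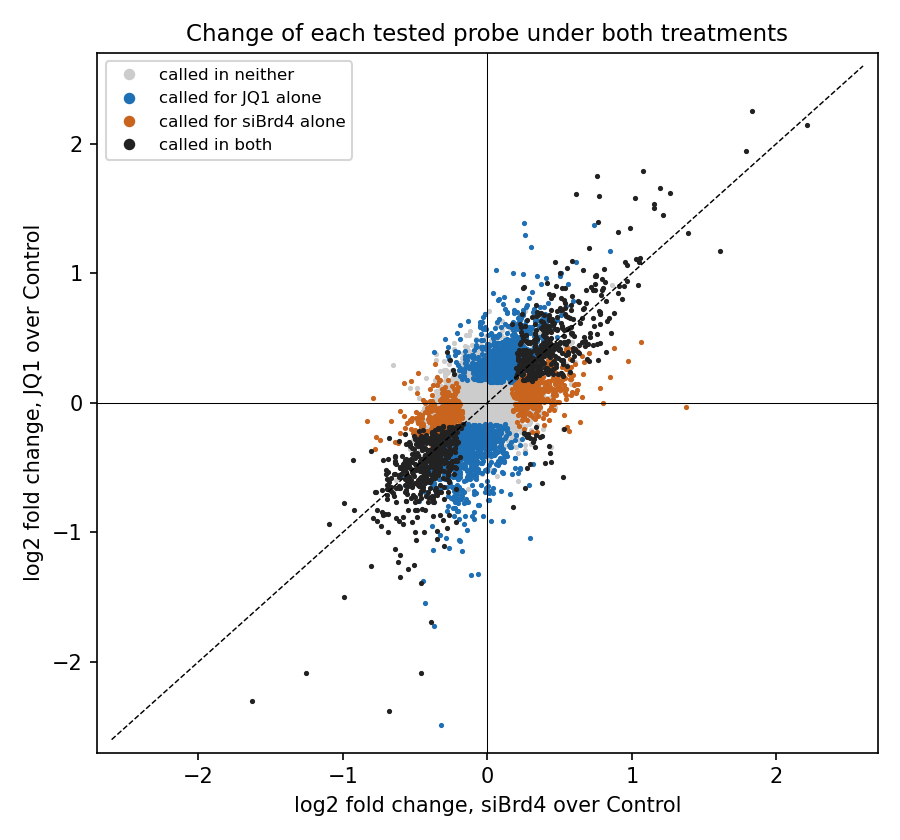
Log2 fold change of each of the 19882 tested probes with siBrd4 (horizontal axis) and with JQ1 (vertical axis) over the same Control arrays, coloured by the comparisons in which the probe was called; the dashed line marks equal change. The 937 probes called in both with the same direction lie in the lower left and upper right, and 28 were called in opposite directions.

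Tested directly against each other, siBrd4 and JQ1 differed at 1355 probes by limma's test, with 753 higher in siBrd4 and 602 higher in JQ1. The siBrd4 arrays were scanned at a detector gain of 37 and the JQ1 arrays at 36. A part played by the gain in these differences was not tested. The 2 largest differences in each direction are those of the fit with the offset of 50. M300005095 was higher in siBrd4, at 1230 ± 152 against 248 ± 56.7 (SD, n = 2 each), with a log2 difference of 2.17 and a standard error of 0.15 (limma adjusted p = 0.00407). Its change with the siRNA alone, -0.32, did not pass (limma adjusted p = 0.287). M200000387 was higher in siBrd4 by 1.70 on the log2 scale (limma adjusted p = 0.00401), although it also fell with the siRNA, by a log2 change of -0.68 (limma adjusted p = 0.0219). M300003595, at 203 ± 15.3 in siBrd4 against 481 ± 63.4 in JQ1, and M300008387, at 545 ± 3.14 against 1132 ± 139 (SD, n = 2 each), were lower in siBrd4. Their log2 differences were -1.14 (limma adjusted p = 0.00828) and -1.03 (limma adjusted p = 0.00407). All 4 missed the threshold without JQ1 replicate 1, at 2.41, 1.82, -1.24 and -1.13 in the order named, and without JQ1 replicate 2, at 1.93, 1.60, -1.04 and -0.92, and M300003595 also missed it without siBrd4 replicate 2, at -1.12. With the brightness around each spot as background none of these 4 differences passed, at 2.24, 1.09, -0.76 and 0.056 in the same order. In the deposited values M400000336, chosen for the siRNA comparison, differed more, at 5.41 times its JQ1 mean in siBrd4, against 4.97 for M300005095 and 3.89 for M200000387, and its fitted log2 difference was 0.84 (limma adjusted p = 0.00302).

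Of the 1355 probes that differed, 424 lay on the same side of Control with the larger change in JQ1, 166 on the same side with the larger change in siBrd4, and 765 on opposite sides of Control, of which 28 were called against Control in opposite directions. Of the 1689 probes called for JQ1 and not for siBrd4, 598 (35.4%) differed between the treatments, and of the 662 called for siBrd4 and not for JQ1, 273 (41.2%) did. The share was 15.7% among the 937 called in both with the same direction, 1.87% among those called in neither and 6.82% of all tested probes. These classes rest on the same treated arrays as the direct comparison, so the shares are no independent test. The count of 1355 was 244 without Control replicate 1, 149 without Control replicate 2, 716 without siBrd4 replicate 1, 88 without siBrd4 replicate 2, and 0 without JQ1 replicate 1 or without JQ1 replicate 2, where limma gave 3337 and 3555 probes at an unadjusted p under 0.05. With the brightness around each spot as background it was 0 (1337 at an unadjusted p under 0.05), with plain subtraction 337, without the offset 622, with only the compared groups in the fit 516, in the deposited values 727, and with median scaling 949 were called, 795 higher and 154 lower in siBrd4. With scaling before an added constant the majority turned, with 598 higher and 695 lower in siBrd4.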

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

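The surrounding brightness as background, scaling before an added constant, normexp without an offset, block medians subtracted and separate Control arrays were chosen after seeing the data. In siBrd4 against Control, the 1627 called probes became 79 with plain subtraction and a floor of 1, 1032 with median scaling, 868 in the deposited values, 592 with only the compared groups in the fit, 540 without an offset and 1 with the surrounding brightness as background. A fold of at least 2 beside the adjusted p left 21 with the offset of 50, against 109 without an offset and 175 in the deposited values, and a fold of at least 2 between all arrays with no test gave 14. In JQ1 against Control, the 2654 became 820 with plain subtraction, 1645 in the deposited values, 1496 without an offset, 1 with the surrounding brightness, 68 with the added fold (294 without an offset, 426 in the deposited values) and 49 with the fold alone. In siBrd4 against JQ1, the 1355 became 337 with plain subtraction, 727 in the deposited values, 516 with only the compared groups, 622 without an offset, 0 with the surrounding brightness (1337 at an unadjusted p under 0.05 in limma), 14 with the added fold (160 without an offset, 244 in the deposited values) and 11 with the fold alone. The 937 shared probes became 55, 357, 386, 287 and 1 with plain subtraction, the deposited values, only the compared groups, no offset and the surrounding brightness. The cause was not tested. With the surrounding brightness, 1353 of 1627, 2256 of 2654 and 1208 of 1355 called probes kept their direction.

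Other settings, apart from single arrays left out, kept the counts by adjusted p alone and the shared count within 1.5 times. Scaling before an added constant gave 2423 probes for siBrd4 and 2904 for JQ1 against Control, of which 478 and 725 rose. The median log2 change of all tested probes in the deposited values was -0.13 for siBrd4 and -0.08 for JQ1.

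Leaving out 1 array gave 1 to 875 probes for siBrd4 against Control, 456 to 2701 for JQ1 against Control, 0 to 716 for siBrd4 against JQ1 (3337 and 3555 at unadjusted p under 0.05 in limma at 0) and 1 to 643 shared probes. The lone array of a group is assumed to vary like the other groups. The correlation of fold changes, 0.65, was 0.54 to 0.68 with 1 array left out, 0.49 with plain subtraction, 0.52 in the deposited values, 0.54 without an offset, and 0.51 and 0.53 with separate Control arrays.

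The replicate numbers are shared by the groups, but no label says that a number marks a common batch, so they were not taken as a pairing. With the replicate number as a block, 1717, 2761 and 1367 probes were called and 971 were shared. The differences between replicates 1 and 2 correlated across probes by 0.01 for Control and siBrd4, 0.11 for Control and JQ1 and 0.16 for siBrd4 and JQ1.

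The 12 log2 fold changes of named probes kept their direction in 251 of their alternatives, and 229 of these stayed past the threshold. The exception in direction was M300008387 in siBrd4 against JQ1, at 0.056 with the surrounding brightness as background, and the cause was not tested. The tests of gene lists and of single genes, and a block for the scan, were not run. In the dimmest bin, 0.830% of probes were called for JQ1 with the offset of 50 and 4.42% without, and the effects of dim signal and offset were not separated.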

Other observations

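Of the tests in this part, that of the shared Control arrays was chosen only after its result was seen, and the alternatives of scaling before an added constant and of block medians were added after seeing the data. More probes fell below the background limit than rose above it, on signals that were not scaled between arrays. With siBrd4, 258 probes were above background on both Control arrays and on neither siBrd4 array, and 73 showed the opposite. With JQ1, 270 were lost and 116 gained. These probes were dim, with a median of 2.51 units in Control, on the scale of the deposited values, among those lost. With the offset that compresses dim changes, limma called 1 of the 258 and 4 of the 270 lost probes. Of the gained probes it called 0 of the 73 and 0 of the 116. Set against the background limit on the scale of the deposited values, 26 of the 258 and 26 of the 270 lost probes were at least 2-fold lower, by at least 7.87-fold and 7.84-fold at the most, and 3 of the 73 and 12 of the 116 gained probes were at least 2-fold higher. The background limit itself was 14.3 and 14.8 units on the siBrd4 arrays, 13.6 and 14.1 on the Control arrays and 13.3 and 13.5 on the JQ1 arrays. The arrays also differed in overall signal, with a median probe signal of 41 and 38 on the Control arrays, 37 and 38 on the siBrd4 arrays and 35 and 35 on the JQ1 arrays, and the counts were not corrected for this.

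The siBrd4 and JQ1 fold changes moved together across probes. Shared Control arrays as the whole source are argued against by the covariance, which was 0.0233 where the highest of 50 simulations of unchanged groups gave 0.00232, and which was still 0.0200 at the smaller of the values with separate Control arrays. The correlation was 0.63 after the medians of each array's 24 blocks were taken off, within 0.1 of the 0.65 before. The large drop set as the sign of trends over the array surface could hardly occur, since shared Control arrays alone gave 0.50 in simulation. The values argue only against shifts of whole blocks as the whole source of the correlation above 0.50. Trends within blocks were not tested. A state common to both Control arrays, such as a culture that differed from the others, was not tested and stays open. With these points open, a common response to the loss of Brd4 from chromatin remains a hypothesis.

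The siBrd4 arrays differed from Control and were scanned at the higher detector gain. A gain effect would follow the brightness of a probe, and a brightness trend was present: with scaling before an added constant, siBrd4 replicates 1 and 2 gave a difference of -0.13 and -0.10 in median log2 change between the brightest and the fifth of 10 bins, and 478 probes rose against 1945 that fell; at equal gain, the same difference was 0.10 between the Control arrays and -0.09 and -0.08 for the JQ1 arrays. A gain effect that follows brightness is argued against as the whole source only. A smooth curve of mean signal explained 1.86% of the variance of the siBrd4 fold changes among the probes called under median scaling. With scaling before an added constant it explained 3.37%. Both shares were taken about the mean change of the called probes, so a shift common to these probes was not tested. The called probes were also selected for large changes both ways, with 423 rises and 609 falls under median scaling. A low share therefore does not limit the part that the gain may have played. Mixed-up single arrays are argued against too, since 6 of the 6 arrays correlated best, after each probe's mean was removed, with the other array of their own group. The part of the falls that follows brightness and a shift common to the called probes stay open. So do an exchange of whole groups and handling that differed between the groups. The knockdown is a candidate explanation that was not tested, since the level of Brd4 was not analysed here.

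Under median scaling, far more probes fell than rose with JQ1, at 2131 against 476, whereas quantile normalization gave 1479 against 1175. When the arrays were scaled first, 24.97% of JQ1 calls rose, against 18.3% under median scaling and 44.3% with quantile normalization. This argues against the offset being added before the scaling as the whole source, and a part played by it stays open. A brightness-dependent difference between arrays cannot be told apart from a true fall of abundant transcripts. Of 10 equal bins of probes by signal, the brightest lay below the fifth by 0.083 in median log2 change with scaling before an added constant. That setting was added after seeing the data, and the value fell between the bounds set for it before this result was seen. Under median scaling itself the difference was -0.15. With scaling before an added constant the difference was 0.10 between the Control arrays themselves, and JQ1 replicates 1 and 2 gave -0.09 and -0.08 against the Control mean.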
